A study of Mus musculus with 12 samples.

How the data were processed

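The samples were single cells of C57BL/6 mouse embryos of 6 morphological stages, profiled for the histone marks H3K27ac and H3K4me1 with CoBATCH, a method in which an antibody brings the Tn5 transposase to marked chromatin and tags the DNA there. The stage names follow the labels: Pre_PS comes before the primitive streak forms; ES, MS and LS embryos carry a short, longer and full streak; OB embryos have no bud of the allantois yet; EHF embryos show the first head folds. Each stage and mark had 1 peak list, so there were 12 lists and no replicates. Per the labels' protocols, extraembryonic tissue was removed from Pre_PS, ES, MS and LS embryos; the labels do not state this for OB and EHF.

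Per the submitters' processing notes, the authors used Bowtie2, Picard, MACS2 and deepTools with the mm10 build. Their versions and settings, the number of cells and the treatment of single cells are not given in the sources used here. The deposited files are broad peak lists. The deposited fold of each peak is the authors' ratio of fragments over the local background, averaged over the peak, and it was used only to describe and rank peaks within a list. The deposited −log10 p and −log10 q values are those of the peak caller used by the authors, and −log10 q was used to rank peaks within a list. The deposited score is 10 times −log10 q without decimals and was not used. Values of single cells were not analysed here.

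Total fragments per library are not given in the sources used here, so the depth was read from the weakest peaks. At the lowest fold and p of a list, fold = (pileup + 1)/(background + 1) and p is the Poisson probability of a higher pileup; whole pileups up to 20 were tried with a tolerance of 0.001 on −log10 p. Each of the 12 lists gave 1 pileup and 1 background. Tested on simulated data, 156 of 160 pairs of pileup and background were recovered as the only solution and the other 4 with a further solution. Peaks at this lowest value are called floor peaks below.

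Peaks on chromosomes 1 to 19 and X were analysed; those on Y, the mitochondrial genome and unplaced sequences were counted apart. Genes were the 21631 protein-coding genes of the RefSeq table of GRCm38, the assembly that mm10 names. That table holds no strand, exons or transcript starts. The plan named transcription start sites, introns and exons; instead, both outer ends of each gene were used, and bases were sorted into those within 1 kb of a gene end, inside genes and between genes. "Far" regions lie over 1 kb from each gene end. The territory of a gene was the set of bases nearer to one of its ends than to an end of any other protein-coding gene, within 100 kb. The share of a gene was the number of covered bp of its territory per covered Mb of the library.

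Sharing between lists was the Jaccard index of covered bases: shared bases over bases covered in either list. Its correlation with the distance in stage order was tested by exact two-sided permutation of the 6 stages (720 orders, smallest possible p 0.00278). For gained and lost regions, the peaks of a mark were merged over stages, and a region was present where a peak overlapped it by at least 1 bp. Gained regions were absent at Pre_PS and ES and present at OB and EHF, and lost regions the opposite. The mean Jaccard index of both marks at the same stage was tested by exact one-sided permutation of the H3K4me1 stages (smallest possible p 0.00139). The order of the marks was tested at far regions with neither mark at Pre_PS and both later, by exact two-sided permutation of the H3K4me1 stages. New far H3K27ac regions were compared with random far regions of the same widths and chromosomes. Shares of peaks carry 95% Wilson intervals, which cover counting error only.

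There were 16 gene lists of 303 genes in all, written before the data were examined, as were the main tests and the rule for named genes: epiblast and pluripotency, primitive streak, nascent and paraxial mesoderm, lateral plate and extraembryonic mesoderm, cardiac mesoderm, blood and endothelium, definitive endoderm and node, neural ectoderm, surface ectoderm and amnion, posterior Hox and Cdx, visceral endoderm, extraembryonic ectoderm and trophoblast, parietal endoderm, primordial germ cells, a housekeeping reference and an adult tissue reference. For 1 symbol, Cripto, no gene was found. The share of each list was correlated with stage order (Spearman's rho and Pearson's r, exact two-sided permutation, Benjamini-Hochberg adjusted over the 32 tests of both marks). Each share was also ranked among 10000 random lists of the same size, matched on mean covered bases in 20 bins. This matching is coarse: the adult tissue list ranged from percentile 0.72 to 99.3 over the H3K27ac libraries. Tested on simulated data, 65 of 2000 random series over 6 stages gave an exact p under 0.05. Tested on simulated data with 21631 genes, a rising list was found at unadjusted p in 20 of 20 simulations of this comparison. The simulated rise was steep and steady, and the simulated peak lists were about equally long at all 6 stages. The simulations therefore do not give the power for smaller or uneven trends, or with a shallow first library.

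The change of a gene was its mean share at OB and EHF minus its mean share at Pre_PS and ES. The named genes were, for each mark, the 10 with the largest positive and the 10 with the largest negative change among genes whose values at OB and EHF both lay on one side of those at Pre_PS and ES; up to 4 members of each list with the largest change under the same condition; the genes nearest to the 5 widest H3K27ac peaks of Pre_PS and of EHF; and 11 genes fixed by name. After the low depth of Pre_PS was seen, the same rule was also run with ES and MS as the early stages. Not all genes chosen by the rule are described, and some of their results are not reported here.

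Alternatives fixed beforehand were the same number of peaks from each list, the upper 50% of each list by −log10 q, bins of 1 kb covered over at least 500 bp, peaks covering at least 50% of a region, gene ends within 500 bp, territories within 50 kb, territories without the bases near gene ends, and leaving out each stage in turn. Alternatives chosen after seeing the data were leaving out floor peaks, taking the same covered bases from each list of a mark for stage sharing, taking ES and MS as the early stages (called "without Pre_PS" for regions and genes), leaving out Pre_PS from the overlap of the marks, and H3K27ac first present at MS or later. Leaving out Pre_PS from stage sharing and list trends was among those fixed beforehand. The computations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.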

Results

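H3K27ac, a mark of active promoters and enhancers, and H3K4me1, a mark of enhancers, were mapped in mouse embryos from before the primitive streak forms to the early headfold. The labels give E6.0 for Pre_PS, E6.0 and E6.5 for ES, E6.0 and E7.0 for MS, E7.0 and E7.25 for LS, E7.25 and E7.5 for OB, and E7.5 for EHF. With 1 library per stage and mark, no difference between stages below could be set against a spread between replicates. In the order of stages, the H3K27ac lists held 13398, 36930, 30072, 39635, 34823 and 33031 peaks over 14.3, 41.4, 35.9, 42.1, 36.4 and 36.2 Mb. The H3K4me1 lists held 36739, 47849, 42344, 45666, 46041 and 35646 peaks over 23.4, 49.4, 44.2, 51.3, 51.0 and 39.1 Mb.

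The Pre_PS libraries were far shallower than the others. Their background at the weakest peaks was 0.0499 fragments for H3K27ac, against 0.211 to 0.330 at later stages (4.22 to 6.61 times as high), and 0.0144 for H3K4me1, against 0.164 to 0.347 (11.4 to 24.1 times as high). At Pre_PS, 24712 of the 36739 H3K4me1 peaks (67.3%) were floor peaks, which rest on a pileup of 1 fragment, and 1927 H3K27ac peaks (14.4%) were floor peaks with a pileup of 2. At later stages floor peaks made up 2.76 to 3.12% of H3K27ac peaks and 2.64 to 9.77% of H3K4me1 peaks.

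**Figure D1:**
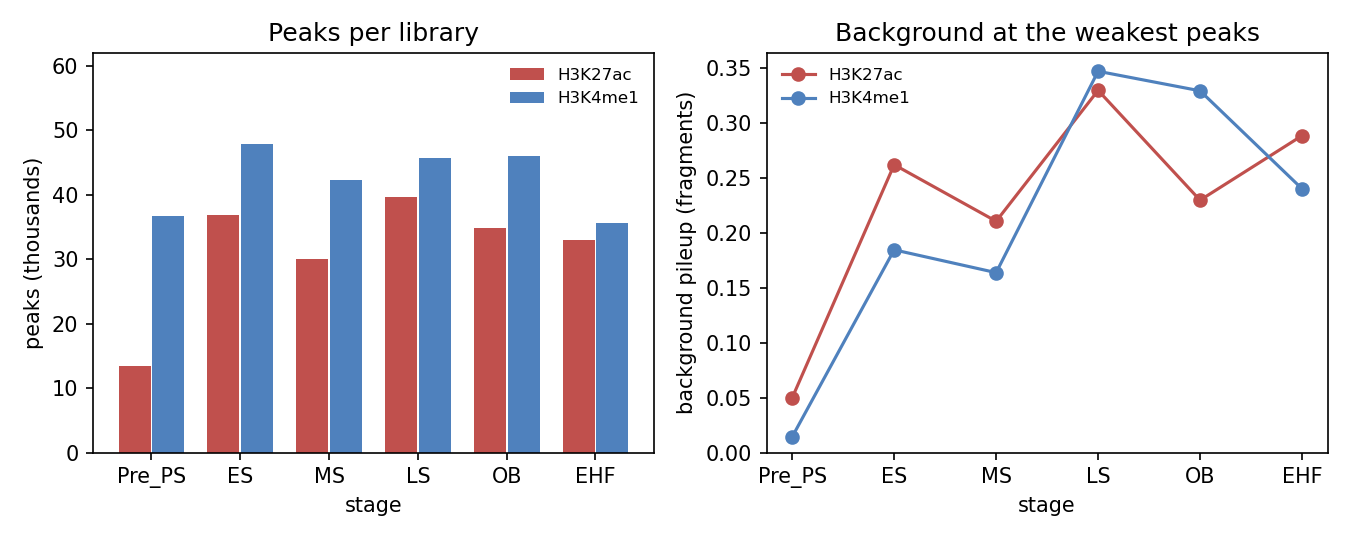
Number of peaks per library (left, bars) and background pileup in fragments at the weakest peaks (right, points) for each stage, H3K27ac in red and H3K4me1 in blue. The Pre_PS libraries have the lowest background, 0.0499 and 0.0144 fragments.

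The widest H3K27ac peak of Pre_PS lay in Plec, which encodes the cytoskeletal linker plectin (chromosome 15, 76172361 to 76183470, mm10), and was 11.1 kb wide with the authors' fold at 3.95. The next widest lay at Hic1, a transcriptional repressor gene (9.14 kb), Zfp628 (8.63 kb), Lfng, a modifier of Notch receptors (8.19 kb), and Crlf2, a cytokine receptor gene (8.02 kb). At EHF the widest peak was 29.7 kb, inside Gse1 with Gins2 as the gene with the nearest end (chromosome 8, 120546925 to 120576576). It was followed by peaks nearest to Pip5k1c (23.0 kb), Sphk2 (17.5 kb), Zbtb7a (17.5 kb) and Apc2 (16.0 kb). Of the EHF peak in Gse1, H3K27ac covered 7.28 kb at Pre_PS and 26.5 to 28.2 kb at the stages between.

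Bases within 1 kb of gene ends made up 53.6% of covered H3K27ac bases at Pre_PS and 36.8 to 41.3% later, and 30.3 to 37.9% of covered H3K4me1 bases over the 6 stages. The median fold of peaks near gene ends was above that of far peaks by 1.25 to 2.85 times for H3K27ac at the 6 stages and by 2.17 to 2.42 times for H3K4me1 at the 5 later stages; at Pre_PS the median fold of far H3K4me1 peaks lies at the floor.

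The first comparison asks which regions stages share. The 5 later stages shared most of their covered bases with one another, and the Jaccard index was lowest with Pre_PS. There the small totals of the H3K27ac and H3K4me1 lists (14.3 and 23.4 Mb) also limit it. The Jaccard index of Pre_PS with later stages was 0.269 to 0.312 for H3K27ac and 0.242 to 0.269 for H3K4me1. Among later stages it was 0.639 to 0.692 for H3K27ac and 0.610 to 0.704 for H3K4me1. Of the Pre_PS H3K27ac bases, 82.0 to 84.4% were also covered at a later stage, within the range of 72.8 to 88.2% between later stages. Of the Pre_PS H3K4me1 bases, 56.5 to 62.2% were, below the 68.4 to 91.1% between later stages. The correlation of sharing with distance in stage order did not pass the exact permutation test for H3K27ac (r = −0.379, p = 0.147) or for H3K4me1 (r = −0.387, p = 0.114). With the same number of peaks from each list, the H3K27ac correlation was −0.411 with exact permutation p = 0.0194. With all peaks but without Pre_PS it was −0.291 (exact permutation p = 0.45).

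**Figure D2:**
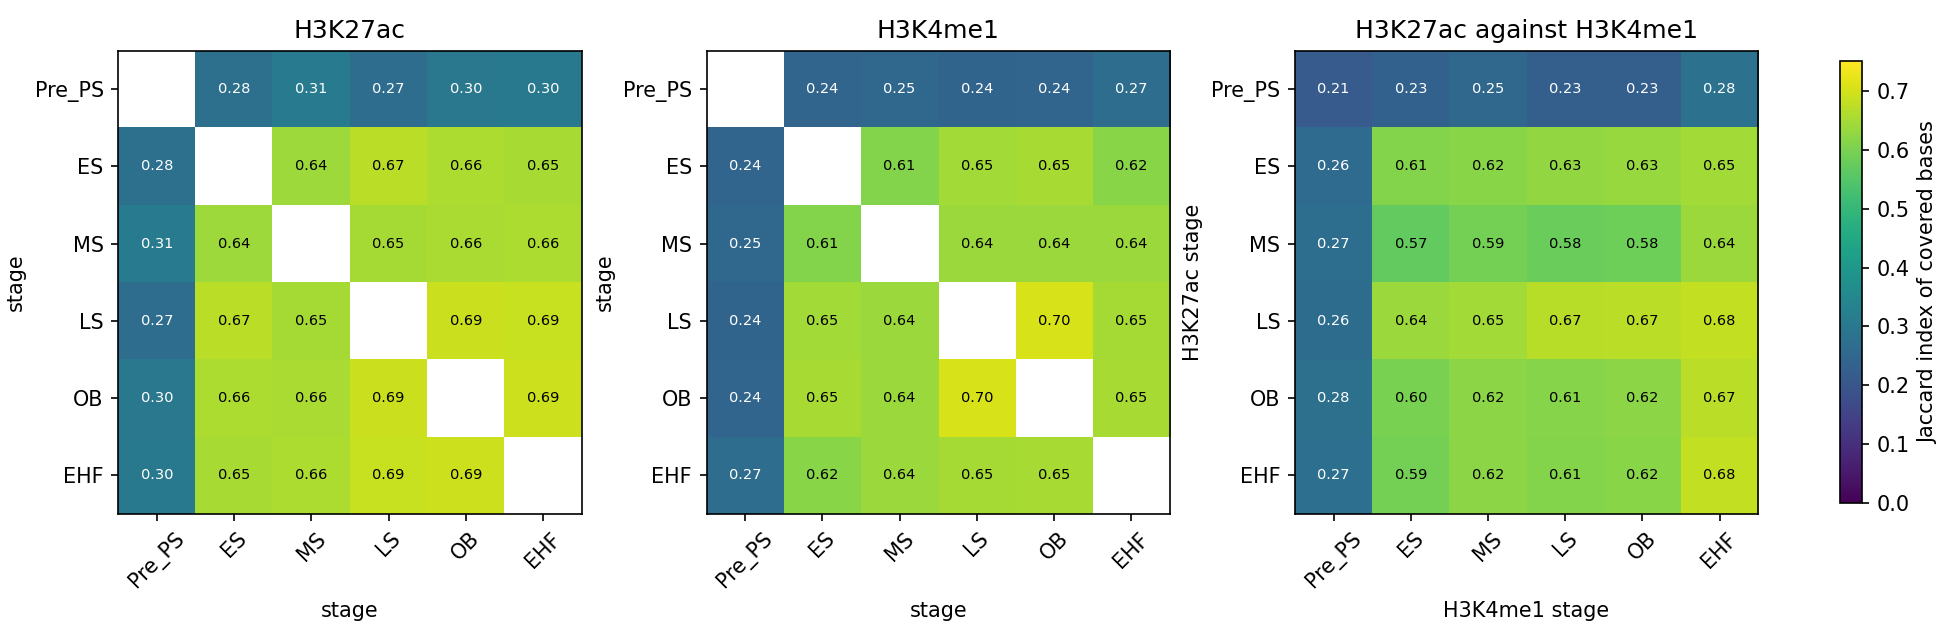
Jaccard index of covered bases between stages for H3K27ac (left) and H3K4me1 (middle), and between the H3K27ac and H3K4me1 libraries of each pair of stages (right). Pairs with Pre_PS are the lowest, and pairs of later stages of a mark lie between 0.610 and 0.704.

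The second comparison asks which regions and genes differ between early and late stages. For H3K27ac, the territories with the largest positive difference in share from Pre_PS and ES to OB and EHF were those of Ccdc85c, Lama5 (a laminin chain), Lmx1b (a homeodomain transcription factor), Gse1, Mvk (mevalonate kinase of the sterol pathway), Prex1 (an activator of Rac), Sbno2, Pxn (the adhesion protein paxillin), Gins2 (a DNA replication factor) and Itpr3 (a calcium channel). The 29.7 kb EHF peak inside Gse1 has Gins2 as the gene with the nearest end, so the entries of Gse1 and Gins2 may not be separate. The largest negative differences were those of Plec, Tmem267, Usp24, Mark4, Adgrb1, Dlgap1, Cdh22, Mid1, Mpp7 and Barhl1. With ES and MS as the early stages, the difference was smaller for each of these genes but Cdh22, where it went from −146 to −236; Prex1 kept 177 of 282 and Mid1 −99.0 of −145. Ccdc85c (chromosome 12, 108203599 to 108277852) held 368 bp per covered Mb at Pre_PS, 1014 at ES, 1107 at OB and 1115 at EHF, from 5.24, 42.0, 40.3 and 40.4 kb of covered bases. Plec held 1589 bp per Mb at Pre_PS, 986 at ES, 968 at OB and 870 at EHF, but its covered length went the other way from Pre_PS, with 22.6, 40.9, 35.2 and 31.5 kb; with ES and MS as the early stages the difference in share was −90.1. The differences of Lama5, Lmx1b, Prex1 and Itpr3 turned negative with the same number of peaks from each list, as did those of Lama5 and Prex1 in the upper 50% of each list, where those of Adgrb1 and Barhl1 turned positive.

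Without Pre_PS, from ES and MS to OB and EHF, H3K27ac was higher around 1700001O22Rik, Prex1, Sh3pxd2a, Ece1 (endothelin-converting enzyme), Cebpb, Ttc7, Rxra (a retinoid receptor), Sdk2, Ppard and Bmp7 (a BMP ligand). Ece1 held 123 and 100 bp per Mb at ES and MS and 269 and 244 at OB and EHF, and Bmp7 (chromosome 2, 172868012 to 172940321) 374 and 372 against 499 and 461. At LS the share of Bmp7 was above those at OB and EHF, so it did not rise steadily to the last stage. Genes around which H3K27ac was lower included Cdh22, Pmepa1, Rbm19, Kcnab2, Plch2, Pax7, Otof and Adgrb1. Pmepa1, known as a TGF-beta-induced inhibitor of SMAD signalling, held 450 and 391 bp per Mb at ES and MS, 419 at LS, and 232 and 223 at OB and EHF; 18.6 kb were covered at ES, 17.7 at LS, 8.45 at OB and 8.06 at EHF. Otof held 152, 103 and 129 bp per Mb at ES, MS and LS and 15.1 and 9.01 at OB and EHF. Of the 20 genes chosen by this rule, 13 kept the direction with the same number of peaks and 16 in the upper 50%. Prex1, Sh3pxd2a, Rxra, Sdk2, Rbm19, Kcnab2 and Pax7 turned in the first of these settings, and Sh3pxd2a, Ece1, Rxra and Otof in the second.

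**Figure D3:**
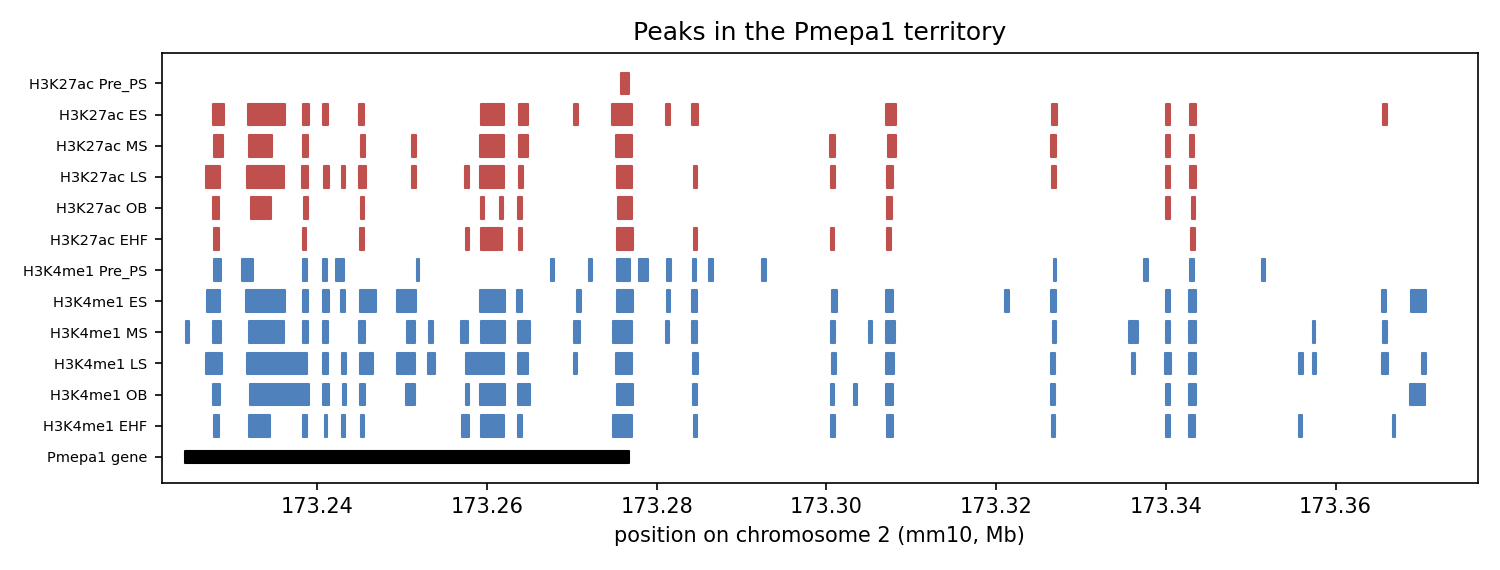
Peaks in the territory of Pmepa1 on chromosome 2 (position in Mb, mm10), with H3K27ac in red, H3K4me1 in blue, 1 line per library and the gene in black. H3K27ac covers 18.6 kb at ES and 8.06 kb at EHF.

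Of 51619 merged H3K27ac regions, 11108 were present at all 6 stages, 1915 were gained and 179 lost. Of all merged regions 70.6% were far from gene ends, of the gained ones 87.9%, of the lost ones 98.9%, of those seen at 1 stage 94.2% and of those present at all stages 24.8%. With ES and MS as the early stages, which drops Pre_PS and adds MS, 1230 regions were gained and 1177 lost. Genes with OB and EHF both above Pre_PS and ES made up 21.0% of the 17442 genes with coverage, and those with both below 9.98%. Chance gives at most 16.7% for each, and less where values tie. With ES and MS as the early stages the shares of genes were 19.9% and 12.6% (3465 and 2196 genes). A pairing against the order of stages, ES and OB against MS and EHF, separated more genes, 3997 and 1880.

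For H3K4me1, the territories with the largest positive difference in share were those of Casz1 (a zinc finger transcription factor), 2900026A02Rik, Zfpm1 (a cofactor of GATA factors), Septin9, Bmp7, Gse1, Ccdc85c, Bahcc1, Ryr1 and Flrt1. Casz1 (chromosome 4, 148804366 to 148954893) held 805 and 1445 bp per Mb at Pre_PS and ES and 1488 and 1561 at OB and EHF, and Bmp7 313 and 535 against 641 and 758. The largest negative differences were those of Slc6a11, Atp2b2, Tmem132e, Rapgef2, D430042O09Rik, Pacs2, Cdh23, Adgrb1, Trio and Gpc1. Much of their early coverage came from floor peaks: the 11.8 kb of Slc6a11 at Pre_PS became 2.35 kb without them, the 10.4 kb of Rapgef2 became 3.82 kb, and the 14.1 kb of Atp2b2 became 0.458 kb, with which its difference turned positive. Without Pre_PS, the difference of Gse1 turned to −5.99. Without Pre_PS, Ccdc85c, Septin9 and Cebpb had the largest positive differences (206, 184 and 174 bp per Mb) and Foxo6 and Adgrb1 were among the largest negative ones (−122 and −114); that of Cebpb turned in the upper 50%.

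Of 77300 merged H3K4me1 regions, 16031 were present at all 6 stages, 1586 were gained, 999 lost and 13688 seen at Pre_PS alone. With ES and MS as the early stages, 951 regions were gained and 1795 lost, and without floor peaks 2048 were gained and 155 lost. The H3K4me1 libraries of ES and MS were also shallower than those of OB and EHF, so depth limits the comparison between them too. Genes with OB and EHF both above Pre_PS and ES made up 18.1% of 18400 genes and those with both below 12.4% (13.9% and 12.8% with ES and MS as the early stages), where chance gives at most 16.7% for each.

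The third comparison asks whether marks gather around genes of particular lineages. For H3K27ac, the surface ectoderm and amnion list had the highest rank correlation of its share with stage, with 1185, 1614, 1800, 1651, 1869 and 1951 bp per Mb from Pre_PS to EHF and 8 of 16 members higher and 1 lower at OB and EHF. Its examples were Gata3 (28.0 and 177 bp per Mb at Pre_PS and ES, 194 and 201 at OB and EHF) and Grhl3, a regulator of epidermal differentiation (0 and 88.6 against 134 and 125). The lateral plate and extraembryonic mesoderm list held 2012, 2525, 2801, 2779, 2717 and 3075, with 9 of 20 members higher and 1 lower; Hand1, a regulator of extraembryonic and cardiac mesoderm, held 33.9 and 182 against 228 and 231, and Bmp4 40.6 and 134 against 193 and 186. In the nascent and paraxial mesoderm list 8 of 22 members were higher and 0 lower, with Snai1, a driver of epithelial-mesenchymal transition, at 185 and 346 against 411 and 375. In the cardiac mesoderm list 7 of 19 were higher and 1 lower, with Smarcd3 at 44.5 and 75.1 against 188 and 126. The neural ectoderm list had 5 of 24 members higher and 2 lower, with Pax6 among the higher ones (121 and 159 against 183 and 186) and as the lower ones Six3, a forebrain regulator, at 406 and 290 against 202 and 226, and Sox11 at 326 and 149 against 123 and 138; Six3 turned in the upper 50%. Pax2, another higher member (583 and 600 against 646 and 644), turned in 4 of 6 alternative settings. In the primitive streak list 4 of 17 members were higher, among them Nodal (0 and 51.7 against 54.5 and 58.3) and Wnt3 (152 and 196 against 200.0 and 200.1), and 2 lower, these being Gsc (215 and 157 against 141 and 133) and Eomes (126 and 130 against 97.8 and 96.4); Gsc turned in the upper 50%, Nodal with ES and MS as the early stages, and Wnt3 there and with the same number of peaks. With ES and MS as the early stages, members higher and lower were 1 and 3 for primitive streak, 6 and 1 for surface ectoderm, 6 and 2 for lateral plate, 5 and 1 for nascent and paraxial mesoderm, 7 and 2 for cardiac mesoderm and 3 and 3 for neural ectoderm.

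No list passed the adjusted threshold in any of the 32 tests (smallest adjusted p 0.178 for Spearman's rho and 0.0889 for Pearson's r, exact permutation). Over 32 tests, 1 list alone reaches an adjusted p of 0.0889 at best, so a trend confined to 1 list could not have passed. At an unadjusted p under 0.05, rho called 2 lists for H3K27ac and 3 for H3K4me1, and r called 6 for each mark. By rho, for H3K27ac these were surface ectoderm and amnion (rho = 0.943, exact permutation p = 0.0167; r = 0.869, exact permutation p = 0.0194; r = 0.657 without Pre_PS and EHF) and trophoblast (rho = 0.886, exact permutation p = 0.0333; r = 0.805, exact permutation p = 0.0444; r = 0.561 without Pre_PS and EHF). By rho, for H3K4me1 these were lateral plate and extraembryonic mesoderm (rho = 0.943, exact permutation p = 0.0167; r = 0.888, exact permutation p = 0.00556; r = 0.899 without Pre_PS and EHF), posterior Hox and Cdx (rho = 0.943, exact permutation p = 0.0167; r = 0.904, exact permutation p = 0.00833; r = 0.805 without Pre_PS and EHF) and trophoblast (rho = 0.886, exact permutation p = 0.0333; r = 0.924, exact permutation p = 0.0139; r = 0.854 without Pre_PS and EHF). In the upper 50% of each list, lateral plate and surface ectoderm for H3K27ac and surface ectoderm for H3K4me1 passed after adjustment (adjusted p = 0.0296, exact permutation), and without floor peaks blood and endothelium for H3K27ac and lateral plate for H3K4me1 (adjusted p = 0.0444, exact permutation). With 1 stage left out, fewer tests had an unadjusted p under 0.05 by rho. They numbered 0 of 32 without EHF, 2 without Pre_PS or OB, 3 without ES and 4 without MS or LS.

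Members of the posterior Hox and Cdx list, which pattern the trunk, had H3K4me1 higher at OB and EHF in 8 of 18 cases and lower in 1. Hoxb6 held 0 and 95.2 bp per Mb at Pre_PS and ES and 126 and 161 at OB and EHF; with H3K27ac it held 34.8 and 64.3 against 82.8 and 125. With ES and MS as the early stages, 7 were higher and 0 lower. In the lateral plate list H3K4me1 was higher for 10 of 20 members and lower for 1 (6 and 1 with ES and MS as the early stages), with Foxf1 at 220 and 315 against 316 and 432 and Msx1 at 128 and 187 against 206 and 252. Irx3 of the neural list held 75.4 and 199 bp per Mb of H3K4me1 against 228 and 245, and Sp5 of the primitive streak list 72.6 and 85.5 against 109 and 139. Gsc, an organizer gene, held 224 and 207 bp per Mb of H3K4me1 at ES and MS against 132 and 159 at OB and EHF.

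Spearman's rho with stage for H3K27ac was −0.0857 for epiblast and pluripotency, −0.771 for primitive streak, 0.829 for nascent and paraxial mesoderm, 0.771 for lateral plate, 0.829 for cardiac mesoderm, 0.429 for blood and endothelium, −0.371 for definitive endoderm and node, −0.429 for neural ectoderm and 0.714 for posterior Hox and Cdx. For the lists of cells that dissection should remove or that are rare, rho was −0.429 for visceral endoderm, 0.771 for parietal endoderm and −0.429 for primordial germ cells; the housekeeping and adult tissue references gave −0.257 and 0.257. For H3K4me1, rho was 0.6 for epiblast and pluripotency, 0.6 for primitive streak, 0.829 for nascent and paraxial mesoderm, 0.657 for cardiac mesoderm, 0.829 for blood and endothelium, −0.314 for definitive endoderm and node, 0.657 for neural ectoderm and 0.657 for surface ectoderm and amnion. It was −0.771 for visceral endoderm, 0.371 for parietal endoderm, 0.486 for primordial germ cells, 0.771 for the housekeeping reference and −0.0286 for the adult tissue reference. The trophoblast list lay at percentile 93.5 to 99.2 of matched random lists for H3K27ac and 98.7 to 99.5 for H3K4me1 at the 6 stages, with Zfpm1 and Wnt7b holding the most covered bases. Without these 2 members the percentiles were 8.36 to 95.4 and 12.9 to 98.0, and 2 of the 12 were at 90 or more. The trend of the difference between marks did not pass for any of the 16 lists, by rho (smallest exact two-sided permutation p = 0.136, adjusted p = 0.726) or by r (smallest exact two-sided permutation p = 0.0333, for neural ectoderm, smallest adjusted p = 0.356).

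**Figure D4:**
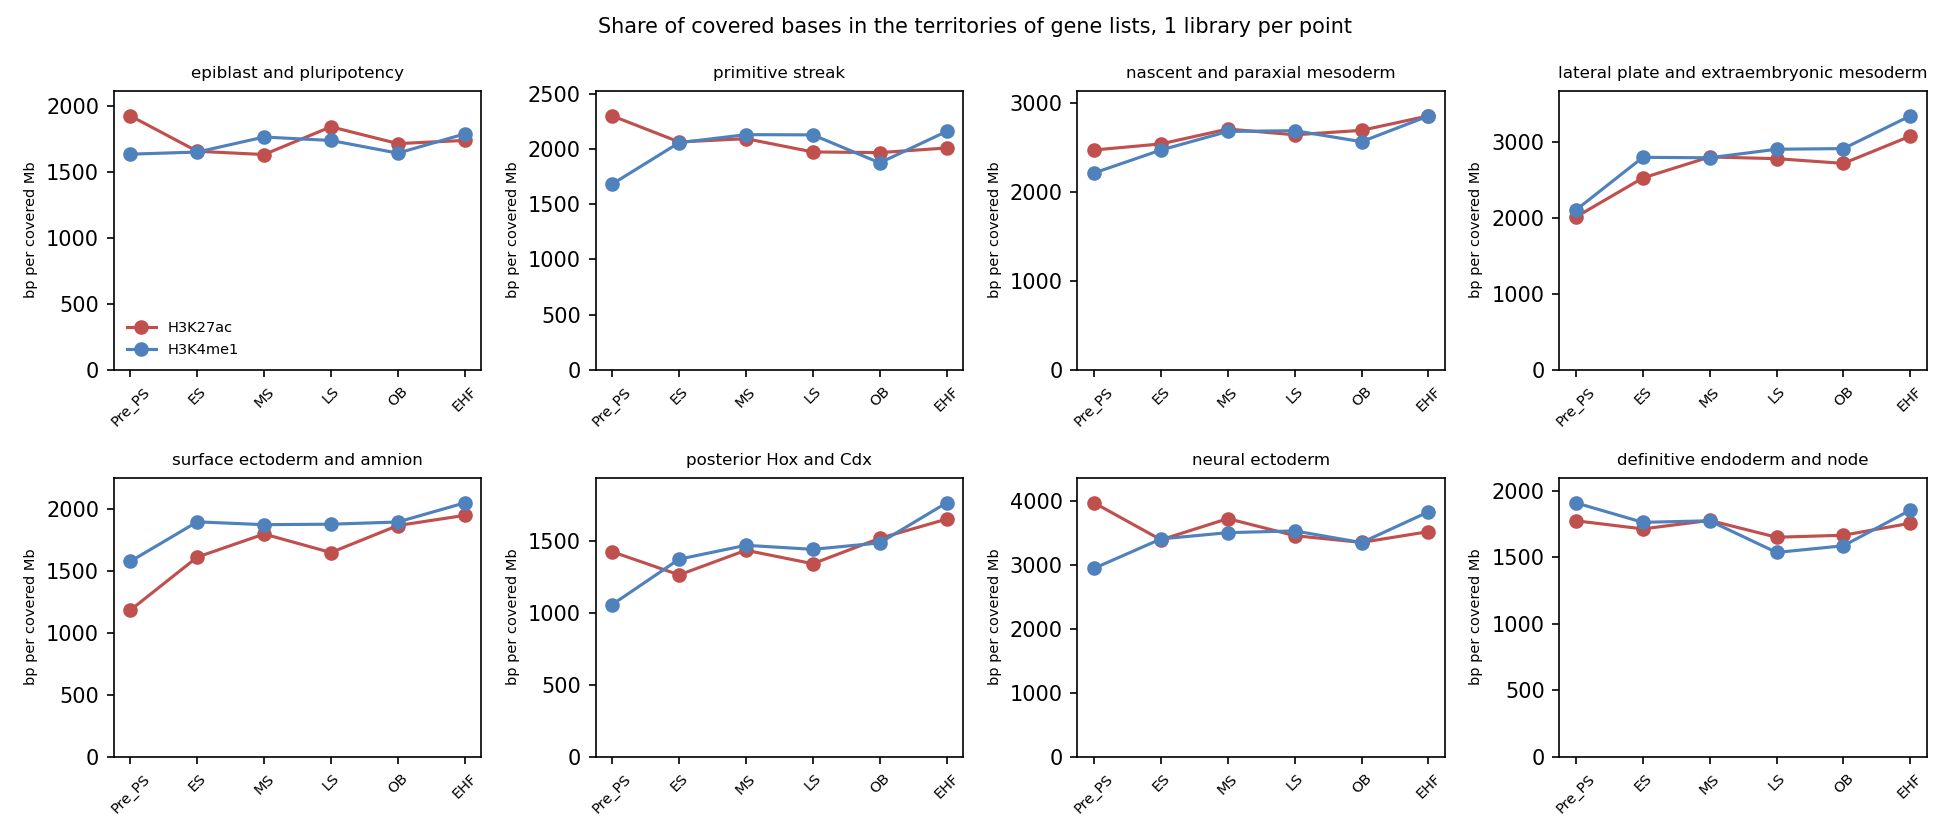
Covered bp per covered Mb of the library in the territories of 8 of the gene lists, by stage, with H3K27ac in red, H3K4me1 in blue and 1 library per point. The H3K27ac share of the surface ectoderm and amnion list is 1185 at Pre_PS, 1614 at ES and 1951 at EHF.

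Genes fixed by name gave the following H3K27ac values. Pou5f1, a core pluripotency factor, had 3.02 kb covered at Pre_PS and 0.855 to 1.01 kb later, but its Pre_PS coverage lay in floor peaks and was 0 kb without them. Nanog held 0 bp per Mb at Pre_PS, 41.0 at ES and 47.7 at EHF. T, the streak and notochord regulator, held 22.2 to 37.8 over the stages and turned with the setting, as did Foxa2 (148 to 219), Sox1 (226 to 316), Gata4 (111 to 154) and Kdr (25.1 to 56.0). Mesp1, expressed in nascent mesoderm, held 55.3 at Pre_PS, 157 at OB and 94.8 at EHF, Sox17 81.4 to 181, and Cdx2 128 to 175.

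At the gene ends of the 259 developmental list genes, H3K27ac was present for 127 genes at Pre_PS, 199 at ES, 190 at MS, 204 at LS, 197 at OB and 198 at EHF. H3K4me1 was present for 159, 205, 202, 210, 208 and 200. For 59 genes no H3K27ac peak was called at Pre_PS and 1 or more at each later stage, and for 51 genes it was absent at all 6 stages, among them Tnnt2, Cer1, Postn and Afp. The table gives only the outer ends of a gene, so a start inside it is missed; Gata3 and Gata4 counted as absent while 7.28 and 5.58 kb of their territories were covered at EHF. Tfap2c, Prdm14, Pax6 and Cxcr4 were among the 59. The housekeeping reference went from 13 to 19 of 20 genes, with Actb, Polr2a and Tbp lacking a peak only at Pre_PS, so a missing peak in that shallow library is not read as absence of the mark. In the lists, gene ends with H3K27ac at EHF numbered 22 of 22 for nascent and paraxial mesoderm, 19 of 20 for lateral plate, 22 of 24 for neural ectoderm, 17 of 18 for posterior Hox and Cdx, 12 of 19 for cardiac mesoderm, 13 of 23 for visceral endoderm, 10 of 19 for trophoblast and 9 of 24 for the adult tissue reference. Among all 21631 genes they numbered 9026 at Pre_PS and 13504 to 14079 later.

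The fourth comparison asks how the marks lie relative to each other. Both marks covered largely the same regions from ES on. At gene ends 96.8 to 98.7% of H3K27ac peaks of the later stages were touched by H3K4me1 of the same stage, and at Pre_PS 78.7% (95% Wilson interval 77.8 to 79.6%). Far from gene ends, H3K4me1 touched 48.9% of H3K27ac peaks at Pre_PS (47.6 to 50.3%) and 77.7 to 88.5% later. H3K27ac touched 10.4% of far H3K4me1 peaks at Pre_PS (10.0 to 10.8%) and 49.8 to 67.6% later. The mean Jaccard index of both marks at the same stage was 0.565, against a mean of 0.512 over the 720 orders of stages (exact one-sided permutation p = 0.00278). For bases far from gene ends it was 0.479 against 0.426 (exact one-sided permutation p = 0.00139, the smallest possible). Most of this gap came with Pre_PS: among the 5 later stages the means were 0.635 against 0.626 (exact one-sided permutation p = 0.0167) and, far from gene ends, 0.550 against 0.538 (exact one-sided permutation p = 0.00833, the smallest possible for 120 orders). Each of the 6 H3K27ac libraries shared most with H3K4me1 of EHF (0.281 to 0.683), and Pre_PS H3K27ac shared least with Pre_PS H3K4me1 (0.214). ES H3K27ac shared less with ES H3K4me1 (0.610) than with H3K4me1 of MS, LS, OB or EHF (0.618 to 0.646). LS H3K27ac shared less with LS (0.670) than with OB (0.674). MS and OB H3K27ac shared more with their own stage than with each stage but EHF. The test did not match covered bases between lists, so like list lengths and regions shared by stage cannot be told apart.

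The last comparison asks whether H3K4me1 precedes H3K27ac at far regions. Of 19448 far regions with neither mark at Pre_PS and both later, 10163 gained both at the same stage, 6452 gained H3K4me1 first and 2833 H3K27ac first. H3K4me1 was thus first at 69.5% of regions with different stages (95% Wilson interval 68.5 to 70.4%). Permuted stage orders gave 54.9% on average and up to 73.5%, and the share did not pass (exact two-sided permutation p = 0.189). Of 31733 new far H3K27ac regions, 37.8% (37.3 to 38.4%) had H3K4me1 at the stage before, against 1.85% of random far regions (1.71 to 2.00%). The share was 31.6% for regions new at ES, after the shallow Pre_PS library, 59.4% at MS, 42.5% at LS, 44.5% at OB and 43.5% at EHF. The random regions lay at any far position and were not drawn from regions that carry a mark at other stages. The gap to them therefore does not tell whether H3K4me1 precedes H3K27ac.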

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

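The tests on short or long peak lists and on fragments of open chromatin were chosen only after the result was seen; the tests on weak peaks and on the trophoblast list were written before.

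Peaks outside the sequences analysed in the report were counted over the 6 libraries of each mark; they are given because the report leaves them out, and they were not tested. H3K27ac had 103 peaks on chromosome Y and 102 on unplaced sequences, and H3K4me1 had 158 and 109.

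The Pre_PS lists shared fewer covered bases with other stages, with a mean Jaccard index of 0.292 against 0.665 among later stages for H3K27ac and 0.250 against 0.644 for H3K4me1. Short Pre_PS lists are argued against as the whole cause for H3K4me1, where with the same covered bases from each list the means were 0.263 against 0.705. In the full lists, 56.5 to 62.2% of the bases of the smaller list lay in the other, against 80.1 to 91.1% among later stages. For H3K27ac the means at the same covered bases were 0.381 against 0.688. In the full H3K27ac lists that share was 82.0 to 84.4% against 79.7 to 88.2%, so list length and other causes cannot be told apart there. For H3K27ac the bound set in advance for weak calls of a shallow library was met, but the test cannot tell them from other causes. Sorted by −log10 q, 97.4% of the Pre_PS peaks in the first of 4 equal groups touched an ES peak and 66.1% in the last. The first groups of later stages reached 99.96 to 100%, but the last groups of MS, LS, OB and EHF only 44.8 to 64.3%. A fall from the first to the last group was thus not particular to Pre_PS. For H3K4me1 the Pre_PS share was 92.6% in the first group, between the bounds of 90% and 95% set in advance, and 28.1% in the last. The last groups of MS, LS, OB and EHF reached 50.5 to 68.5%. Weak calls and other causes cannot be told apart there either. A difference of the stage itself, before the streak forms, stays open and untested, since the only Pre_PS library of each mark is also the shallowest.

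Both marks shared about as many covered bases at the same stage, 0.594 to 0.683 from ES on, as stages of a mark did. With the same number of peaks from all 12 lists the mean over the 6 stages was 0.572, against 0.565 with all peaks, so shorter lists did not share less. Such lists keep the peaks of highest −log10 q, which lie more often near gene ends, where the marks overlap most. Of the ES H3K27ac peaks, 1773 of 9232 in the first of 4 groups by −log10 q were far, and 8396 of 9233 in the last. The test therefore cannot tell what long lists add among weak far peaks. Fragments of open chromatin in the libraries of both marks, which Tn5 is known to produce, could contribute: the median fold of H3K4me1 peaks was higher near gene ends than far from them at each of the 5 later stages, by at least 2.17 times, while at Pre_PS the far median lies at the floor. That test mixes gene starts with gene ends, since the gene table holds no strand. Regions that carry both marks in the same cells stay open and untested.

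The trophoblast list lay at percentile 93.3 to 99.0 of matched random lists for H3K27ac and 98.7 to 99.6 for H3K4me1, as drawn for this test. Without Zfpm1 and Wnt7b, the 2 members with the most covered bases, the percentiles were 8.36 to 95.4 and 12.9 to 98.0, and 2 of the 12 were at 90 or more. The high rank thus rests largely on these 2 members. The matching itself was not refined, so coarse matching of these members and a truly high share of both cannot be told apart. The count was made the deciding number only after the highest percentile had been seen, while the bound on most stages was set before. A contribution of extraembryonic cells at OB and EHF, for which the labels state no dissection, was not tested.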

How the results depend on the processing

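Leaving out floor peaks, the same covered bases from each list, ES and MS as early stages ("without Pre_PS" for regions and genes), the overlap of the marks without Pre_PS, and H3K27ac first present at MS or later were chosen only after the data were seen; the other alternatives were planned. With 1 library per stage and mark, depth limits each comparison with Pre_PS, and no spread between replicates is known. For H3K4me1, depth also limits the comparison of ES and MS with OB and EHF, since the ES and MS libraries were shallower. No paired analysis was possible because no replicate numbers link libraries of different stages; the marks were compared within stages. The correlation of sharing with stage distance kept its sign in all alternatives; leaving out 1 stage at a time it was −0.421 to −0.291 for H3K27ac and −0.426 to −0.328 for H3K4me1, and only with the same number of peaks (−0.411) and with the same covered bases (−0.422) did it pass for H3K27ac. The same-stage overlap of the marks passed in all 4 alternatives (0.479 to 0.635), but none of them matched covered bases between lists. The order of the marks passed in none (63.2 to 77.2%). Counts at gene ends stayed within 1.5 times.

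Gained and lost H3K27ac regions, 1915 and 179 in the report, were 509 and 342 with the same number of peaks, 533 and 75 in the upper 50%, 1230 and 1177 without Pre_PS, while lost regions were 283 as 1 kb bins and 113 without floor peaks. For H3K4me1, 1586 and 999 in the report, they were 348 and 532 in the upper 50%, 2542 and 283 as 1 kb bins, 951 and 1795 without Pre_PS, and lost regions were 155 without floor peaks. With ES and MS against OB and EHF, 2407 H3K27ac and 2746 H3K4me1 regions differed; the other pairings of these stages gave 2285 and 1809 for H3K27ac and 3830 and 2366 for H3K4me1, so for H3K4me1 the early-to-late pairing was not the largest. For genes it was the largest for neither mark: it separated 5661 and 4922, and ES and OB against MS and EHF 5877 and 7300. H3K4me1 at the stage before new H3K27ac was 35.9% with the same number of peaks, 26.0% where it covered 50% of the region and 47.2% from MS on. Lists past the adjusted threshold numbered 3 in the upper 50% of each list and 2 with floor peaks left out, against 0 in the report and in each other setting, and rho differed in sign for 0 to 6 of the 32 tests. The cause of these differences was not tested, apart from fewer peaks under the stricter settings.

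Of the single genes run under the alternatives, these changed sign (differences in bp per Mb). With the same number of peaks, from Pre_PS and ES, H3K27ac gave −18.5 for Lama5, −182 for Lmx1b, −43.9 for Prex1, −99.7 for Itpr3, −25.6 for Hoxc4, −30.0 for Col4a2, −161 for Wnt3, −289 for Pax2, 6.03 for T and 9.89 for Kdr; from ES and MS, −3.75 for Prex1, −128 for Sh3pxd2a, −34.0 for Rxra, −55.4 for Sdk2, 12.7 for Rbm19, 4.48 for Kcnab2 and 9.07 for Pax7. In the upper 50%, from Pre_PS and ES, H3K27ac gave −21.7 for Lama5, −100.5 for Prex1, 124 for Adgrb1, 57.7 for Barhl1, 128 for Six3, −16.1 for Pax2, 61.2 for Gsc, 20.1 for Pou5f1, 21.6 for T, 115 for Sox1, −24.9 for Gata4 and 25.6 for Kdr; from ES and MS, −23.8 for Sh3pxd2a, −12.7 for Ece1, −3.68 for Rxra and 3.35 for Otof, and H3K4me1 gave −5.89 for Cebpb, −148 for Pitpnm2 and 69.4 for Meltf. Without bases near gene ends Fgf5 gave 8.15 and Pax2 −68.6. Without floor peaks Pou5f1 gave 13.6 and, for H3K4me1, Atp2b2 30.6. Without Pre_PS, H3K27ac gave 1.60 for Pou5f1, 1.46 for T, 29.5 for Foxa2, 12.2 for Sox1, −34.3 for Wnt3, −3.23 for Nodal and −7.38 for Pax2, and H3K4me1 −5.99 for Gse1. Some list and fixed genes not run under the other alternatives also changed sign without Pre_PS. Among them were, for H3K27ac, Tbx6 (−2.76), Wnt7b (−7.12) and Amn, which turned positive, and for H3K4me1 Spry4, Hcn4, Pecam1, Pth1r, Prdm1, Polr2a, Pou5f1, Nanog and Mesp1. This is not a full list. The cause was not tested, except that without floor peaks Pou5f1 and Atp2b2 lost most or all of their Pre_PS coverage.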

Other observations

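All tests in this part were chosen only after the result was seen, and the genes in it were chosen after their values were seen.

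Some genes had more kb covered at Pre_PS than at each later stage, in spite of the shallower libraries. For H3K27ac these were 608 of 17442 genes, or 414 with floor peaks left out. Rmdn2 had 4.94 kb at Pre_PS and 1.12 to 1.64 kb later, Ogfrl1 3.92 against 1.12 to 1.68 kb, and Fam219b 2.99 against 0.899 to 1.05 kb, with the same values without floor peaks. Snai2, a regulator of epithelial-mesenchymal transition, had 2.35 kb against 0.719 to 1.24 kb, and Mixl1, a primitive streak gene, 1.84 against 1.26 to 1.51 kb, also without floor peaks. So did the housekeeping gene Rpl13, with 2.935 kb against 1.171 to 2.497 kb, and the list genes Amn and Hoxa5. Whether the genes wider at Pre_PS share a theme was not tested. Pou5f1 was among the 10 largest with all peaks but had 0 kb at Pre_PS without floor peaks, and of those 10 genes 6 stayed wider. For H3K4me1, 1649 of 18400 genes were wider at Pre_PS with all peaks and 199 without floor peaks. Dnmt3b, a de novo DNA methyltransferase of the epiblast, had 2.57 kb of H3K4me1 at Pre_PS, or 2.28 kb without floor peaks, against 1.63 to 1.82 kb later.

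A hypothesis was that target genes of Nodal signalling lose H3K27ac as a group between ES and MS and OB and EHF, prompted by Pmepa1, Gsc and Eomes. A list of 18 known targets, written after some members had been seen and sharing 9 genes with the primitive streak list, held 2056 bp per Mb at ES and MS and 1904 at OB and EHF, with 6 members lower and 1 higher. Its difference lay at percentile 4.08 of 10000 matched random lists with all peaks, but at 10.5 with the same number of peaks, 42.9 in the upper 50% and 6.61 without floor peaks. For H3K4me1 the percentiles were 2.67, 1.66, 24.4 and 2.77, while 2 members were lower and 3 higher. The other pairings of these stages gave 47.6 and 43.7 for H3K27ac and 54.0 and 15.7 for H3K4me1 with all peaks. These values partly restate what prompted the list. Without its members Gsc and Eomes the percentiles were 8.46, 24.3, 68.2 and 12.7 for H3K27ac and 10.5, 5.64, 38.03 and 6.95 for H3K4me1, so no loss around Nodal targets as a group is read from them.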
